A study of Magallana gigas with 6 samples.

How the data were processed

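Messenger RNA was measured in mantle tissue of oysters from an F2 population that descends from crosses of Crassostrea angulata females with Crassostrea gigas males (C. gigas is listed as Magallana gigas). Per the series description, 458 F2 animals were genotyped and sampled at 11 months of age, and RNA of 40 animals with high and of 40 with low content of EPA+DHA was mixed in equal amounts, with 3 technical replicates per group. EPA and DHA are the long-chain omega-3 fatty acids eicosapentaenoic and docosahexaenoic acid. By that description each group rests on 1 set of 40 animals, and the p-values measure the spread between libraries, not the spread between oysters. The coefficient of variation beyond counting noise was 10.9% among the high and 41.4% among the low libraries. Whether the low libraries are repeats of 1 RNA mix is therefore open, and with it what their SD and n stand for.

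Poly(A) RNA was captured from total RNA, fragmented, copied to cDNA and amplified by PCR into Illumina libraries, per the labels' protocols. Neither strand marking nor molecular identifiers are mentioned there. The deposited table holds raw read counts per gene for 6 libraries, whole numbers with totals that differ between libraries. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The table lists 34871 genes, 30342 with identifiers that start with Cg and 4529 with identifiers that start with XLOC, and 4479 of them had 0 reads in all 6 libraries. It held 0 rows that name no gene and 0 columns of other samples. The columns of the low group carry the library names of the labels. The columns of the high group were matched by the group letter of the series description and the replicate number of the title, since the labels name those libraries by another letter.

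The table pairs no identifier with a gene name. Of its 34871 identifiers, 0 matched the RefSeq gene table of the assembly xbMagGiga1.1, which lists 33331 genes. The comparison, the alternatives, the naming rule and 29 gene lists were fixed before the data were examined. The lists, that of long-chain fatty acid synthesis among them, are defined by product names and none of them could be applied. Genomic positions and gene functions are not reported for the same reason. Genes that share reads with a near-identical copy, or that overlap another gene on either strand, are uncertain, since neither the treatment of such reads nor the use of strand is given.

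Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, R 4.3.3) with TMM factors after filterByExpr, which left 17809 genes. The 3 high libraries were compared with the 3 low libraries with no other term in the model. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of high over low, and standard errors were approximated as the fold change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library size. The common biological coefficient of variation of edgeR was fitted within each group with TMM factors. Median chi-square values of library pairs were taken over genes with more than 50 reads in the pair. They were scaled by the reads of those genes, without TMM factors. Library totals and shares were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3. Total counts ran from 9788187 to 12751690 reads per library. Counting intervals and floors cover counting error only, because PCR reads are not independent molecules. For a gene with 0 reads in a whole group, the fold is a bound against 3 reads over that group, which is 0.0759 CPM in the low and 0.104 CPM in the high group. Bounds without a library were computed for libraries of the group with reads.

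The naming rule took the called genes with at least 5 CPM in every library of the higher group and no overlap between the groups. For a table without product names it took the 2 with the highest and the 2 with the lowest fold change. The procedure was tested on simulated data with 200 changed genes, real means and depths and each group's own dispersion. All genes of a group shared that dispersion and libraries were drawn independently, so the recovery and the false calls hold for that setting. Of 66 genes simulated at each size, 10.6% were recovered at 2-fold, 72.7% at 4-fold and 100% at 16-fold, with 2 false calls among 16990 unchanged genes of the 17188 tested there. The alternatives were the RLE factors, library size alone, no count filter, a filter of CPM 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, leaving out the 20 most abundant genes, glmTreat against 1.5-fold, and leaving out each library. Voom with quality weights per group, thinning to equal depth and leaving out a run of genes in identifier order were added after seeing the data, as were the principal components, the spread within groups and the groupings by identifier.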

Results

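Gene expression was profiled in the mantle, the tissue that lines the oyster's shell, of F2 hybrids of Crassostrea angulata and Crassostrea gigas chosen from the extremes of EPA+DHA content. The high and the low EPA+DHA group were each represented by pooled RNA of 40 oysters and by 3 libraries described as technical replicates. The high libraries 1, 2 and 3 held 10250561, 10160893 and 9788187 counted reads, and the low libraries 1, 2 and 3 held 12751690, 12524221 and 11703483. Between 25057 and 26494 genes had at least 1 read in a library. Depth was 10066547 reads ± 245201 (SD, n = 3) in the high and 12326465 ± 551376 (SD, n = 3) in the low group. With 3 libraries against 3, the exact permutation p for depth was 0.1, the smallest possible, and 0.4 after Benjamini-Hochberg adjustment over the 4 library measures compared.

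The first comparison was among the libraries of each group. The 3 high libraries were close to one another in expression, with Pearson correlations of log2 CPM across genes from 0.977 to 0.979. The 3 low libraries were not, with correlations of 0.952 between low libraries 1 and 2, 0.914 between 1 and 3 and 0.891 between 2 and 3. Genes are not independent replicates in these correlations. The coefficient of variation beyond counting noise was 10.9% in the high and 41.4% in the low group, a ratio of 3.79, although the libraries of either group are described as repeats of 1 RNA mix. The median chi-square of read counts was 0.918 to 1.09 per gene between high libraries and 5.86 to 19.5 between low libraries. Counting alone gives 0.455 if the scale is right. The scale was the reads of the pair without TMM factors, which were 0.947 to 0.961 for the high and 1.12, 1.27 and 0.810 for low libraries 1, 2 and 3. The values between low libraries therefore include that difference in scale. With TMM factors, the coefficient of variation of pairs, as a fraction, was 0.0975 to 0.115 (high) and 0.302 to 0.490 (low). No pair of libraries of a group therefore agreed within sampling noise, and all 6 were kept as separate libraries.

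Low library 3 stood apart from the other low libraries. On the first principal component, with 50.03% of the variance, the high libraries lay between -53.1 and -47.5, low libraries 1 and 2 at 61.3 and 81.8, and low library 3 at 6.05. On the second, with 27.8%, low library 3 lay at -90.0 and the other 5 libraries between 9.90 and 28.3. Its correlation with the 3 high libraries was 0.914 to 0.921, at or above its correlation of 0.914 with low library 1 and 0.891 with low library 2.

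**Figure D1:**
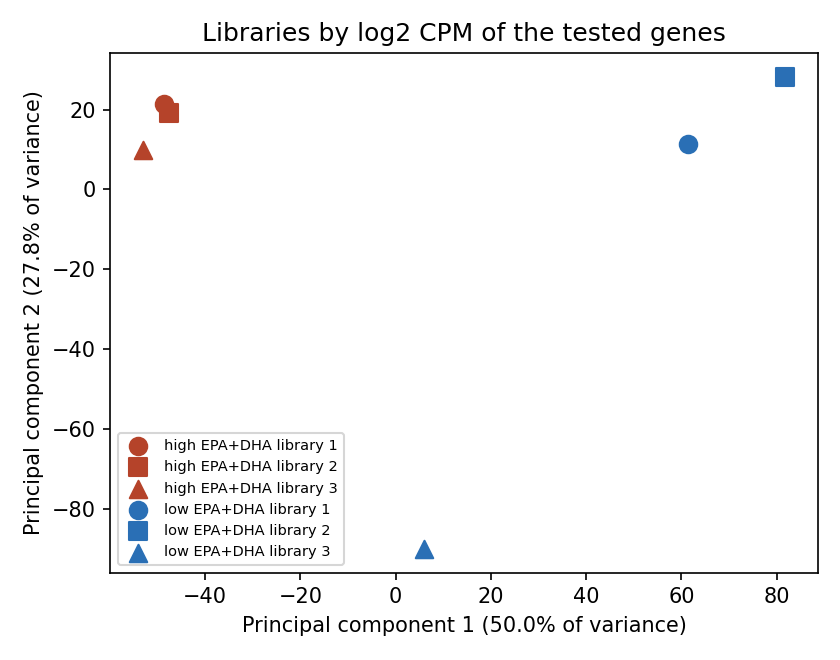
Principal components of log2 CPM over the 17809 tested genes, with 1 point per library, red for high and blue for low EPA+DHA, and the replicate number as the marker shape. The high libraries lie together, low libraries 1 and 2 lie at 61.3 and 81.8 on the first axis, and low library 3 lies at 6.05 on the first and -90.0 on the second.

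The comparison that the design is built on asks which mantle genes differ between oysters high and low in EPA+DHA. Of 17809 genes tested, 459 were higher and 295 lower in the high group (edgeR quasi-likelihood test, adjusted p under 0.05), and 4.23% of genes were called in all. Of these, 407 were at least 2-fold higher and 236 at least 2-fold lower. Genes that rose did so by a median log2 fold change of 2.24 (interquartile range 1.44 to 3.23), and genes that fell changed by a median of 1.37 (1.06 to 2.18). All 459 risen genes were higher in each high library than in each low library, and all 295 fallen genes were lower. Changes of at least 16-fold were found in 81 risen and 28 fallen genes. The counts changed when 1 library was left out. Without low library 3, 2809 genes were higher and 2586 lower, 1610 and 1396 of them at least 2-fold, and 744 of the 754 genes called with all libraries were among them. Without low library 1 the counts were 191 and 161, of which 185 and 152 were at least 2-fold. Without high library 1, 2 or 3 they were 66 and 3, 53 and 2, or 78 and 3, all at least 2-fold. The loss was alike for each high library, so it was not particular to 1 of them. The test fits 1 dispersion per gene to both groups, whose spreads were 10.9% (high) and 41.4% (low). Leaving out a high library also changes that fit, and the 2 effects were not separated.

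The risen genes took up 3.20% ± 0.177 of reads in the high libraries and 1.03% ± 0.0666 in the low libraries (SD, n = 3 each). The fallen genes took up 0.819% ± 0.00951 in the high and 5.92% ± 3.37 in the low libraries. Their shares in low libraries 1, 2 and 3 were 3.00%, 5.15% and 9.60%. The most abundant fallen gene averaged 375 CPM ± 4.56 in the high group and reached 4398, 7802 and 38818 CPM in low libraries 1, 2 and 3. Its log2 fold change was -5.50 ± 0.85 (SE), with an adjusted p of 0.0185 by the quasi-likelihood test of edgeR. Without low library 3 the change was -4.02, which is 16.2-fold against 45.3-fold. The most abundant risen gene averaged 2693 CPM ± 29.5 in the high and 737 CPM ± 277 in the low group, a log2 fold change of 1.87 ± 0.31 (SE) at an adjusted p of 0.0213 in the same edgeR test. Without high library 1, 2 or 3 neither gene passed the threshold, with adjusted p by edgeR of 0.123, 0.135 and 0.124 for the fallen and 0.123, 0.132 and 0.123 for the risen gene. The call of the risen gene was also lost without low library 1 (adjusted p = 0.0716, edgeR). Over the fits without 1 library, adjusted p ran from 2.5e-05 to 0.135 for the fallen and from 0.000286 to 0.132 for the risen gene. Both were singled out after their values were seen.

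Across all genes tested, 5259 genes (29.5%) had groups that did not overlap, where chance gives 10% if all libraries vary alike. The libraries did not, with a spread of 10.9% in the high and 41.4% in the low group. Chance can then exceed 10%, so no conclusion is drawn from the difference. The simulation at this depth and spread recovered 10.6% of 2-fold changes. It gave all genes of a group the same dispersion, unlike the real genes, so that share holds for the simulated setting only.

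**Figure D2:**
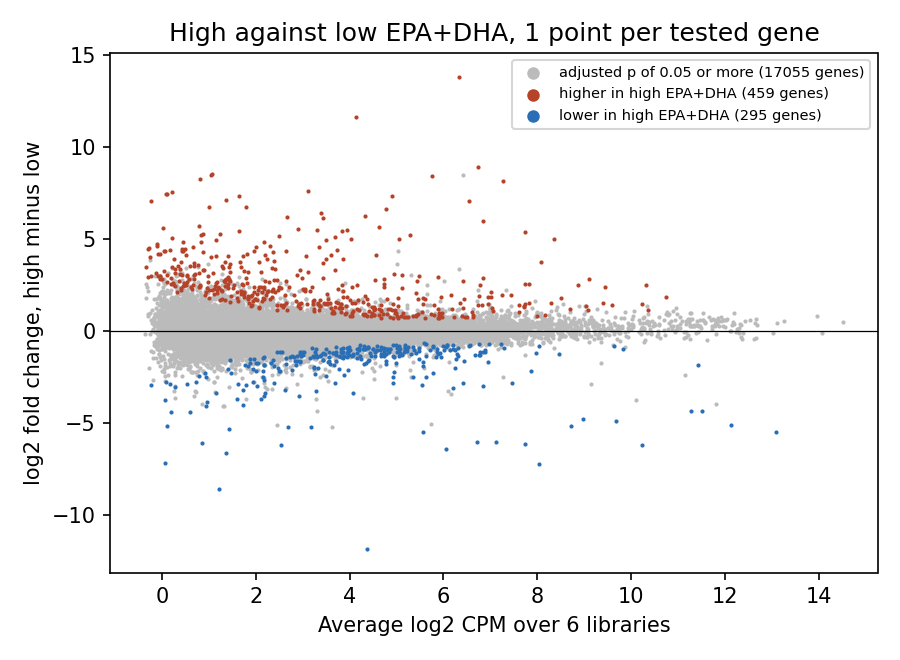
Log2 fold change of high over low EPA+DHA against average log2 CPM, with 1 point per tested gene, red for the 459 genes called higher and blue for the 295 called lower. The called genes spread over the whole range of abundance, and the fitted changes beyond 10 on the log2 axis belong to genes with 0 reads in 1 group.

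Calls were spread over genes of all abundances. Of the genes with a mean under 1 CPM, 5.73% were called, against 3.33% at 1 to 10 CPM, 5.03% at 10 to 100, 6.58% at 100 to 1000 and 5.88% at 1000 CPM or more. Genes with a mean under 1 CPM passed the count filter more readily when 1 group was higher, which can raise their share. At 1 to 10 CPM more genes rose (229) than fell (89), and at 10 to 100 CPM 162 rose and 166 fell.

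The genes with the highest fold changes under the naming rule were Cg28977 and XLOC_035033. Cg28977 had 3899, 519 and 276 reads in high libraries 1, 2 and 3 and 0 reads in every low library, so that it was at least 2111-fold higher (adjusted p = 0.0269, edgeR quasi-likelihood test). Its level differed between the high libraries, at 160 CPM ± 205 (SD, n = 3), and without high library 1 the bound was 551-fold. The call was lost without high library 2 (adjusted p = 0.0916 in edgeR) and without low library 1 (0.0742), 2 (0.108) or 3 (0.157). Over all 16 alternatives its adjusted p ran from 2.6e-08 to 0.698, and it was called in 9. XLOC_035033 had 309, 331 and 365 reads in the high libraries and 0 in the low libraries, with 35.1 CPM ± 4.08 in the high group. It was at least 462-fold higher (adjusted p = 0.000466, edgeR) and was called in all 17 alternatives, with adjusted p from 1.4e-17 to 0.00949.

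The genes with the lowest fold changes were XLOC_027524 and Cg19695. XLOC_027524 had 0 reads in the high libraries and 82, 263 and 956 in low libraries 1, 2 and 3, and was at least 394-fold lower (adjusted p = 0.0449, edgeR). Without low library 3 the bound was 107-fold. That call was lost without any 1 of the high libraries 1, 2 and 3 (adjusted p of 0.152, 0.158 and 0.157 in edgeR) and without low library 2 (0.149). Over all 17 alternatives its adjusted p ran from 1.7e-05 to 0.343, and it was called in 11. Cg19695 averaged 3.49 CPM ± 0.353 in the high and 522 CPM ± 374 in the low group. Its log2 fold change was -7.22 ± 0.57 (SE), a 149-fold lower level, with an adjusted p of 0.00177 by edgeR, and it was called in all 17 alternatives, with adjusted p from 1.4e-57 to 0.0243. Without low library 3 its log2 fold change was -6.45, which is 87.2-fold.

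Of the 295 fallen genes, 50 were highest in low library 1, 140 in low library 2 and 105 in low library 3. Among the 20 with the lowest fold changes under the conditions of the naming rule, 19 were highest in low library 3 and 1 in low library 2. Of the 459 risen genes, 133 were highest in high library 1, 142 in high library 2 and 184 in high library 3. Among the 20 with the highest fold changes, the numbers were 11, 3 and 6, and 10 of these 20 belonged to a run of genes that lie together in the order of their identifiers.

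Genes with XLOC identifiers were compared with genes with Cg identifiers, a grouping chosen after the table was seen. Of 1747 XLOC genes tested, 103 rose and 24 fell, and of 16062 Cg genes 356 rose and 271 fell. The share of risen genes among the called was 81.1% for XLOC and 56.8% for Cg identifiers (Fisher's exact test, two-sided p = 1.5e-07, over genes, which are not independent replicates). The median log2 fold change was 0.31 for XLOC and -0.08 for Cg genes. As a set, the XLOC genes were called higher by camera with the preset correlation (p = 1.0e-07) and not with an estimated correlation (p = 0.226). XLOC genes held 4.61%, 4.67% and 4.72% of reads in the high libraries, 3.53% and 3.65% in low libraries 1 and 2, and 4.67% in low library 3 (exact permutation p = 0.2 between the groups, two-sided). The median log2 fold change of XLOC genes was 0.57 without low library 3 and 0.19 with scaling by library size alone, where the median of all genes moved from -0.06 to -0.21.

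Cg28977 lay in the run of genes in identifier order, which holds 20 tested genes with consecutive places among the tested genes in the order of their Cg numbers, all with a log2 fold change of 1 or more. The span lists 62 genes, of which 42 were not tested. The run was singled out after its values were seen. Of its genes, 18 were called higher, and 19 were higher in each high library than in each low library. The median log2 fold change was 6.19 with the 2 genes without reads in the low group at their bounds, which is 72.9-fold, and the lowest was 3.66. The span held 0.437%, 0.200% and 0.0989% of reads in high libraries 1, 2 and 3 and 0.00536%, 0.00336% and 0.00432% in low libraries 1, 2 and 3. Its genes varied more between the high libraries than other genes did, with a median SD of 1.23 on the log2 scale against 0.18 over all tested genes. Without high library 1, the median fitted log2 fold change fell from 6.74 to 5.59.

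**Figure D3:**
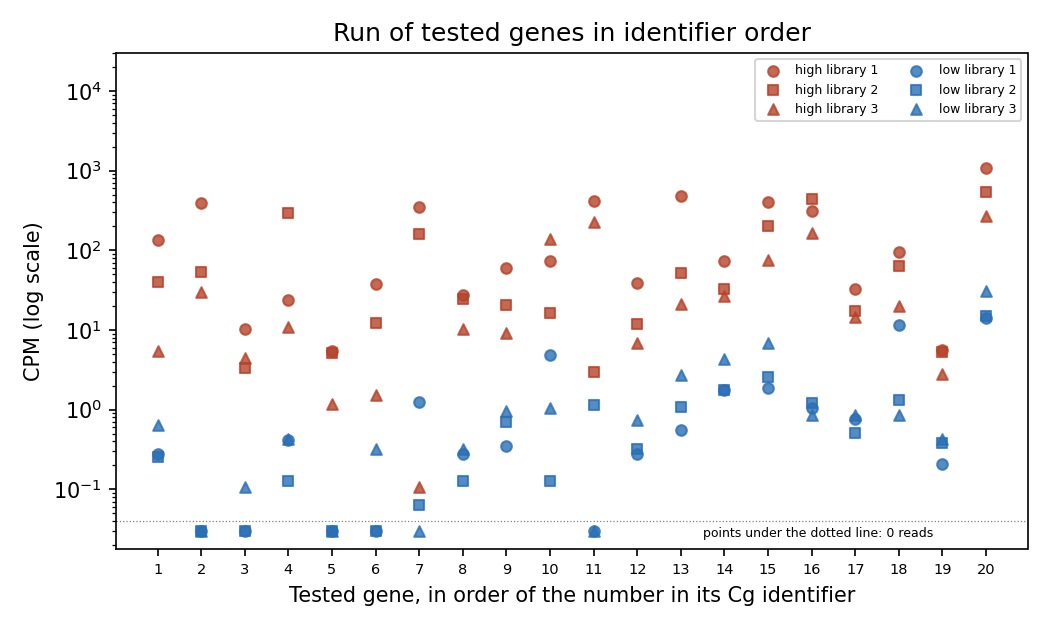
CPM on a log axis of the 20 tested genes of the run, in the order of their numbers, with 1 point per library, red for high and blue for low EPA+DHA, and points under the dotted line for 0 reads. In 19 of the 20 genes every high library lies above every low library, and the high libraries differ from one another by amounts that change from gene to gene.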

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

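The fits with quality weights per group, thinned libraries and the run of genes in identifier order left out were chosen after seeing the data. Of 180 values recomputed under alternatives, 131 kept their side of the threshold or stayed within their margin. Only the fold changes of the named genes could count as reversed, and 0 did. Those genes were chosen for wide gaps between the groups, so that 0 says nothing about the other values. DESeq2 called 937 genes higher and 691 lower, 773 and 536 of them at least 2-fold. The lower count was 190 with library size alone and 514 with quality weights per group. For at least 2-fold lower genes it was 150 with limma-voom and 371 with quality weights. The test against 1.5-fold gave 169 higher and 49 lower. Leaving out 1 library gave 53 (without high library 2) to 2809 (without low library 3) higher and 2 to 2586 lower genes. At least 2-fold, these were 53 to 1610 and 2 to 1396. The cause was not tested. Library size alone moved the median log2 fold change of all genes from -0.06 to -0.21. The replicate block gave 472 higher and 276 lower genes, and same-numbered libraries deviated with correlations of 0.0575, 0.0530 and 0.163, so the numbers were not taken to pair the libraries. High library 1 correlated best with low library 2 (0.0781), while high libraries 2 and 3 correlated best with the low library of their own number. Pairs of unlike number had correlations from -0.123 to 0.0781, so a weak pairing is not excluded. Cg28977 was past the threshold in 9 of 16 alternatives (adjusted p from 2.6e-08 to 0.698) and XLOC_027524 in 11 of 17 (1.7e-05 to 0.343). The planned results for gene lists were not run, because no identifier has a name. At this depth, simulated 2-fold changes were recovered at 10.6% with each group's own dispersion and at 87.9% with that of the high group in both. Thinned to 9788187 reads each, the libraries gave 451 higher and 282 lower genes.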

Other observations

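The tests in this part were chosen after the first results were seen, the one on thinned libraries before its own result. They take up the number of changed genes, the place of low library 3 and the run of genes in identifier order.

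The high and low groups differed in 754 genes, and the groups also differed in depth. After thinning every library to the lowest total, 733 genes passed the threshold, 688 of them shared with the full data, which argues against depth as the cause. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes, for higher, lower and at least 2-fold changed genes alike. The highest of the other splits called 0 genes by edgeR, with up to 1575 at an unadjusted p under 0.05, against 3978 for the real split. With 10 splits no share under 0.05 can be reached.

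By correlation, low library 3 lay slightly nearer the high libraries than the other low libraries did. Its correlations with them were 0.914 to 0.921, against 0.906 to 0.912 for low library 1 and 0.881 to 0.889 for low library 2. That does not hold by every measure. On the second principal component low library 3 lay at -90.0, the high libraries between 9.90 and 21.3, and low libraries 1 and 2 at 11.5 and 28.3. Of the 20 genes with the lowest fold changes under the conditions of the naming rule, 19 were highest in low library 3 and 1 in low library 2. Another measure took 5210 of the 5395 genes called without low library 3, those also tested with all libraries. Over these its median place on the log2 scale was 0.727 of the way from low libraries 1 and 2 to the high libraries. These genes were called because low libraries 1 and 2 differed from the high libraries, a choice that pulls the left-out library toward the high ones. The places of low library 1 (0.203, 349 of 352 genes) and low library 2 (-0.0207, 572 of 575 genes), taken in the same way, rest on other genes, and over the 754 genes called with all libraries, a choice that favours low libraries close together, low libraries 1, 2 and 3 lay at 0, -0.162 and 0.149. A high library under a wrong label is argued against by its highest correlation with a high library, 0.921 across genes, where the high libraries correlated at 0.977 or more. RNA of the high pool mixed in would bring genes near absent from low libraries 1 and 2 to about the mixed share of their high level. In low library 3, 21 such genes outside the run reached a median of 5.29% of that level (interquartile range 2.47% to 10.4%). These values argue against a mixed share far above that range. The share is on the CPM scale and the place at 0.727 on the log2 scale, so the 2 are not directly comparable. What share that place would need was not computed. Separate preparation of low libraries 1 and 2 cannot be told apart from a difference between the RNA of the low libraries: the labels give no batch, the 2618 genes called with these 2 against the other 4 restate the place of low library 3, after which that split was chosen, and no biological explanation was tested.

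The run of 20 tested genes in identifier order was a median of 72.9-fold higher in the high group, with the 2 genes without reads in the low group at their bounds. Its median fitted log2 fold change, which uses no bounds and is not on the same basis, fell from 6.74 to 5.59 without high library 1. Chance order of the identifiers is argued against: the longest run in 10000 permuted orders was 7 genes (permutation p = 1e-04, the smallest they can give). Long runs were not limited to risen genes. The longest run of tested genes at least 2-fold lower held 8 genes, and no permutation was run for that direction. A single RNA source with its genes in 1 ratio is argued against by the shares of the run's reads, which differed between the high libraries by a median ratio of 2.35. The largest ratio, 557, came from a gene at 353 CPM in high library 1 and 0.108 CPM, near the floor, in high library 3. Its size is therefore uncertain. The ratio that counting noise alone would give was not computed. Uneven amplification of a few molecules, gene by gene, is argued against as the whole cause, since 17 of the 20 genes were highest in high library 1 (85.0%, exact Clopper-Pearson 95% interval 62.1% to 96.8%, where unrelated genes give 33.3%). A source whose amount and makeup both differ between libraries, sequence from another organism, a variant against the reference and the difference between the pools in EPA+DHA stay open and were not tested, and the last would not by itself account for differences between libraries described as repeats of 1 pool.

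Between the tested genes that flank the run, 68 listed genes were left out of the test by the count filter. Of these, 34 had reads in the high libraries, 6141 reads in all, and 14 had reads in the low libraries, 168 in all.

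A hypothesis from the run is that genes with neighbouring numbers tend to change together elsewhere too. Outside the run, 38 of 10942 pairs of neighbouring Cg numbers were called in the same direction and 4 in opposite directions. Permuted orders gave a median of 8 and at most 21 same-direction pairs (permutation p = 1e-04, the smallest that 10000 permutations can give). The rank correlation of fold changes between neighbours was 0.0679 across pairs, above the 0.0422 reached by the permutations, so the tendency is small. It may be that neighbouring numbers mark neighbouring or similar genes, and whether they do was not tested.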
